A study of Marchantia polymorpha with 17 samples.

How the data were processed

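Total RNA of Marchantia polymorpha plants was measured on 17 two-colour Agilent arrays on 3 slides. Per the labels' protocols, 200 ng of total RNA per sample was amplified and labelled with Cy3 or Cy5, and each replicate was an independent pool of 6 to 8 plants. The experimental RNA carried Cy3 on 11 arrays and Cy5 on 6. Per the file headers, the slides were scanned at 3 micron and read with Agilent Feature Extraction 10.7.3.1.

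The deposited scanner files hold, per the file headers, the mean intensity of each spot and the median intensity of its local background, without normalization. They also hold processed intensities, which per the file headers Feature Extraction made by background detrending, linear and lowess dye normalization and surrogates for low values. The log10 ratios of red over green were made from the processed signals, per the file headers. The flags for spots well above background, saturated spots and outliers were set by Feature Extraction, per the file headers. The deposited series matrix holds log2 ratios of experiment over control, and the labels do not state how the authors normalized them.

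The main values were computed from the mean and background intensities with limma 3.58.1 in R 4.3.3, and data.table (version 1.17.8). Background was corrected by normexp with an offset of 50, ratios were normalized within arrays by loess with weight 0 for the 1319 control spots and for outliers, and outlier spots were set to missing. Of 60103 spots for 40422 probes, 26684 probes were kept as well above background in either channel on at least 2 arrays. Probes were averaged per locus, over isoforms, which left 13912 genes of 19217 loci. The array annotation describes 9131 of them (65.6%), and 0 of the array's gene names matched the reference table, so names come from the array alone. The number of arrays and the share of spots above background limit the precision.

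Groups, comparisons, tests, gene lists, the rule for named genes and most of the other settings were fixed before the data were examined. Each gene was tested with limma (lmFit and eBayes, two-sided) on log2 ratios of experiment over control, in 1 fit over the 17 arrays with 1 coefficient per comparison and a dye effect per gene. The fit has 10 residual degrees of freedom and a prior of 3.68. Where 1 array of a comparison is left out, the arrays that remain are assumed to vary like those of the other comparisons. The p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. The 4 differences between comparisons were tested as contrasts of the same fit. Slides 1, 2 and 3 are the only batches visible in the labels and files: OPDA in Tak-2 lies on slide 1, wounding on slide 2, Mpcoi1-1 against Tak-2 on both, and the other comparisons on slide 3.

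Of 29 gene lists, defined by words in the array descriptions (the male sex chromosome by gene names), 27 had at least 5 tested genes. The polyphenol oxidases had fewer and the female sex chromosome list was left empty, so neither was tested. The lists were tested against the other genes with camera at a correlation of 0.01 and with an estimated correlation, adjusted over the lists within each comparison. Named genes were chosen by a rule: per comparison the 10 largest rises and the 10 largest falls among called genes with the same sign on every array and an informative description, the same description counted once. To these came up to 3 members with the smallest adjusted p of each list that passed camera, MpCOI1 and MpJAZ everywhere, and 5 genes each way for the differences. Overlaps of called genes were set against the count expected of independent lists and against simulated unchanged samples.

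The procedure was tested on simulated data: of genes changed 2-fold in the simulation, 89.6% were called in the right direction with 3 arrays, 71.6% with 2 arrays and 37.3% for the difference of OPDA responses (at 1.5-fold 40.3%, 25.4% and 5.97%), and of 13712 unchanged genes 2, 8 and 1 were called. The simulated noise was independent and had the same spread for a gene on every array. It leaves out arrays of unequal quality and correlation between genes or arrays. The alternatives were no background subtraction, an offset of 10, processed signals of Feature Extraction, scaling between arrays, no filter or a filter on every array, no dye term, only the arrays of a comparison, the replicate number as a block, slide as a random block, the brightest probe, array weights, series matrix values, a variance trend, a fold of at least 2 beside the threshold, and each array left out. A dye effect per slide, the arrays of 1 slide only and slide as a fixed block were added after the data were seen.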

Results

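The 17 arrays compared pairs of RNA samples from the liverwort Marchantia polymorpha. The RNAs of a pair carried Cy3 and Cy5 and shared 1 array, in 6 comparisons of 3 arrays each, except 1 with 2 arrays. The plants were the female wild type Tak-2, the male wild type Tak-1 and 2 mutants of MpCOI1, which encodes the F-box protein of the jasmonate-type receptor: Mpcoi1-1 (female) and Mpcoi1-2 (male). A further line carried the Arabidopsis receptor gene AtCOI1 in Mpcoi1-1. In the red channel 48.5% to 58.7% of spots lay well above background on each array. In the green channel 45.1% to 53.0% did so on slide 3, and 21.2% to 42.6% on slides 1 and 2. The number of arrays limits the precision of every value. Changes are given as folds or as log2 ratios ± standard error (SE) from limma, with n = 3 arrays unless stated. The SE rests on the spread over all 17 arrays of the fit. It is therefore alike for the 3-array comparisons of a gene and does not show how well their own arrays agree. "Rose", "fell" and "differed" stand for an adjusted p under 0.05. Gene symbols are those of the array annotation, which names the most similar Arabidopsis protein.

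Of the 13912 genes tested, 1147 passed the test for OPDA in Tak-2 and 1913 for OPDA in Mpcoi1-2. For Mpcoi1-1 against Tak-2 1983 passed, for Mpcoi1-2 against Tak-1 815, for wounding 3318 and 460 for the AtCOI1 line with coronatine. The probes of a gene differed in sign for 10 of 1108, 4 of 1884, 14 of 1922, 3 of 806, 20 of 3231 and 0 of 457 of these genes with several probes, in the same order.

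**Figure D1:**
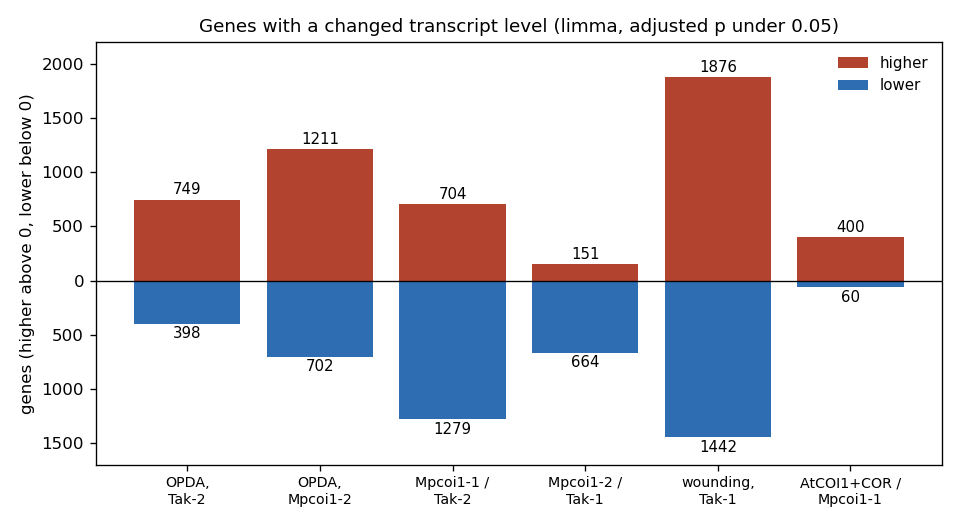
Number of genes past an adjusted p of 0.05 in each comparison (bars, counted upward from 0 for genes higher in the first-named sample and downward for genes lower in it). Wounding has 1876 higher and 1442 lower genes, and the coronatine comparison 400 and 60.

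OPDA, a cyclopentenone of plastid fatty acid origin from which flowering plants make jasmonate, was compared with mock in Tak-2 at 25 µM for 2 h, to ask which genes respond in plants with a functional receptor. Genes for small heat shock proteins, which hold unfolded proteins in solution, rose among the most. HSP20-like Mapoly0057s0019 rose 15.3-fold (3.93 ± 0.37, adjusted p = 2.32e-05), HSP17.6A Mapoly0010s0145 8.34-fold (3.06 ± 0.24) and BAG6 Mapoly0035s0113, a cochaperone, 6.59-fold (2.72 ± 0.28). VEP1 Mapoly0190s0002, an NAD(P)-binding reductase, rose 16.1-fold (4.01 ± 0.41), and the glutathione S-transferases GSTF10 Mapoly1812s0001, 7.93-fold (2.99 ± 0.27), and GSTU8 Mapoly0031s0032, 4.44-fold (2.15 ± 0.17), each above background on 2 of 3 mock samples. PLP5 Mapoly0106s0023, a patatin-like lipase, rose 7.09-fold (2.83 ± 0.40, with 4.60, 3.44 and 0.90 on replicates 1, 2 and 3). MpJAZ Mapoly0097s0021, the repressor that the receptor targets, rose 1.89-fold (0.92 ± 0.15, adjusted p = 0.00123). TLP9 Mapoly0170s0003 fell 4.13-fold (-2.05 ± 0.23), the carbonic anhydrase ACA5 Mapoly0012s0065 2.70-fold (-1.44 ± 0.15, above background on 2 of 3 treated samples) and the cation exchanger CHX19 Mapoly0011s0034 2.59-fold (-1.37 ± 0.22).

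Of the gene lists fixed in advance, 7 shifted against the other genes under OPDA in Tak-2. Heat shock and chaperone genes rose for 37 of 138 and fell for 1 (41 and 3 adjusted over the list alone; mean 0.48, median 0.10; camera adjusted p = 8.29e-09, and adjusted p = 0.0303 with an estimated correlation). Of 12 WRKY transcription factors 4 rose (7 adjusted over the list alone; adjusted p = 0.000174, and adjusted p = 0.0369 with an estimated correlation), WRKY20 Mapoly0008s0159 by 2.09-fold. Of 69 phenylpropanoid and flavonoid genes 16 rose and 1 fell (18 and 2 adjusted over the list alone), among them the polyketide synthase Mapoly0071s0075 at 6.41-fold and CAD9 Mapoly0517s0001, a lignin-pathway dehydrogenase, at 3.79-fold. The list had an adjusted p = 0.000389, and adjusted p = 0.289 with an estimated correlation. Of 32 jasmonate and oxylipin biosynthesis genes 9 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 0.000685, and adjusted p = 0.187 with an estimated correlation). OPR1 Mapoly0097s0082, an OPDA-reducing enzyme, rose 5.21-fold, a lipoxygenase, Mapoly0106s0031, 3.94-fold and the acyl-CoA oxidase ACX1 Mapoly0169s0009 1.80-fold. Glutathione and redox genes rose for 16 of 102 and fell for 1 (17 and 1 adjusted over the list alone; adjusted p = 0.0226, and adjusted p = 0.187 with an estimated correlation). Histone genes fell for 2 of 10 (3 adjusted over the list alone; adjusted p = 0.0125, and adjusted p = 0.187 with an estimated correlation), histone H1-3 Mapoly0035s0095 by 0.83 on the log2 scale. The 8 chlorophyll biosynthesis genes included none past the test (1 lower adjusted over the list alone), with a list mean of -0.23 (adjusted p = 0.0203, and adjusted p = 0.134 with an estimated correlation).

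Of the 1147 genes that differed, 749 were higher and 398 lower. With only the 3 arrays of the comparison in the limma fit 0 passed (1239 at an unadjusted p under 0.05), which ended the call of every gene named above. With the arrays of slide 1, on which all 3 lie, 323 passed (257 higher, 66 lower), and MpJAZ, OPR1, the lipoxygenase and the glutathione list no longer did. MpJAZ (Mapoly0097s0021) also missed the threshold without background subtraction (0.41). Across genes, which are not independent replicates, the dye-swapped replicate 3 correlated with replicates 1 and 2 at r = -0.09 and -0.16, and they with each other at 0.81. Without replicate 3, 1992 genes passed (745 higher, 37.4% in place of 65.3%), without replicate 2, 757 (579 higher), and without replicate 1, 522 (396 higher). The chlorophyll list did not pass without replicate 3 (adjusted p = 0.435, 0.00705 to 0.435 over its settings).

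**Figure D2:**
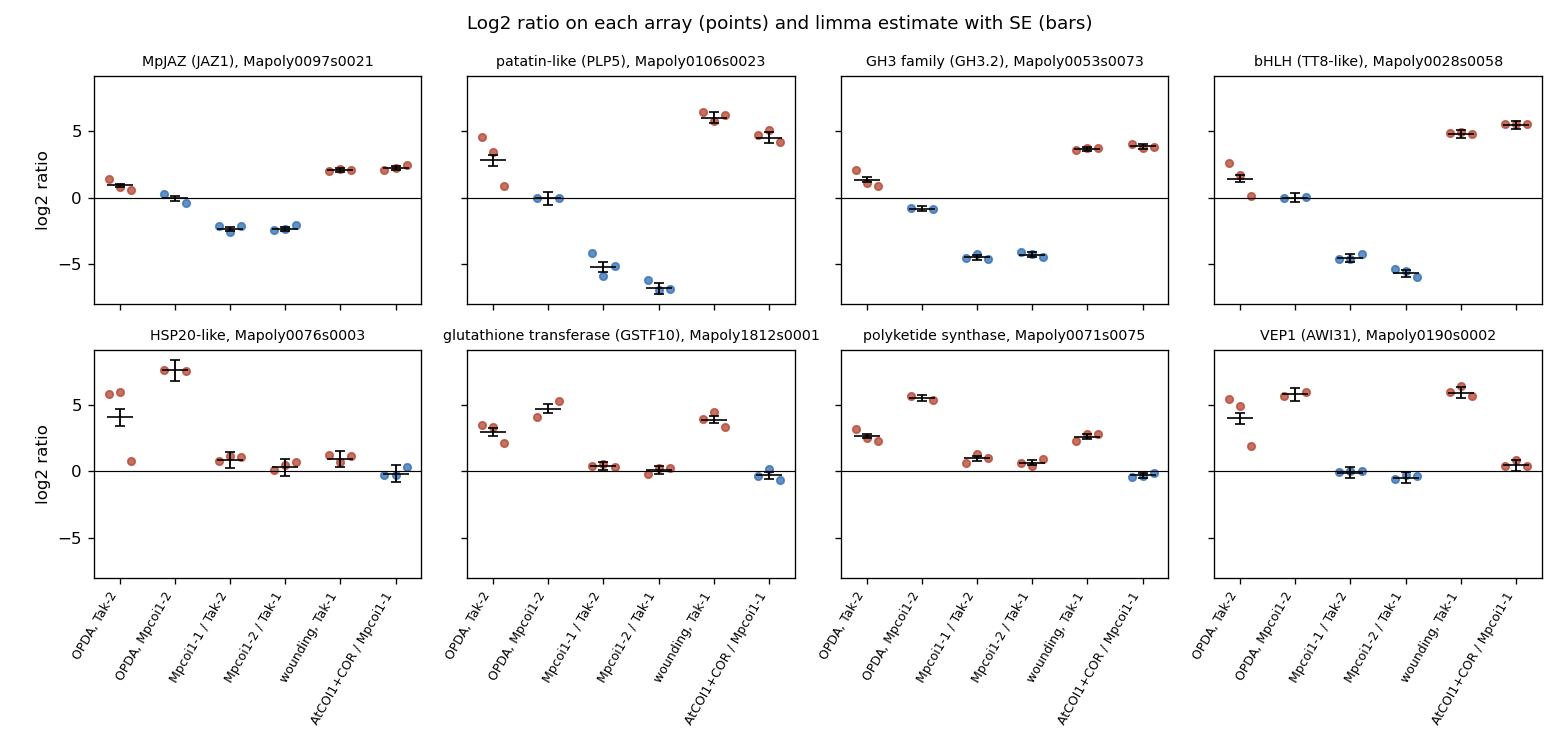
Log2 ratio of each array (points) with the limma estimate ± SE (bar) for 8 genes in the 6 comparisons. MpJAZ was near 0 under OPDA in Mpcoi1-2 (-0.04) and at -2.34 and -2.35 in the mutants against wild type, and HSP20-like Mapoly0076s0003 at 7.63 under OPDA in Mpcoi1-2.

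OPDA was also compared with mock in Mpcoi1-2 (n = 2 arrays), to ask which genes respond in plants without the receptor. The largest rises among the named genes were those of heat shock genes. HSP20-like Mapoly0076s0003 rose 199-fold (7.63 ± 0.77), HSP20-like Mapoly0076s0006 155-fold (7.28 ± 0.28, adjusted p = 3.08e-09), HSP17.6A Mapoly0010s0142 136-fold (7.09 ± 0.59). HSP21 Mapoly0045s0146, a plastid protein, rose 79.0-fold (6.30 ± 0.53) and HSP101 Mapoly0033s0015, which dissolves protein aggregates, 26.5-fold (4.73 ± 0.30). VEP1 rose 57.7-fold (5.85 ± 0.49), the polyketide synthase Mapoly0071s0075 46.6-fold (5.54 ± 0.22, above background on 1 of 2 mock samples), GSTF10 26.7-fold (4.74 ± 0.33) and ECP63 Mapoly0087s0018, a late embryogenesis protein, 31.6-fold (4.98 ± 0.36). CHX19 fell 10.2-fold (-3.35 ± 0.27), the carbonic anhydrases ACA4 Mapoly0012s0070 and ACA5 8.77-fold (-3.13 ± 0.35) and 8.47-fold (-3.08 ± 0.18), and the iron oxidase LPR2 Mapoly0186s0019 5.28-fold (-2.40 ± 0.21). MpJAZ had a log2 ratio of -0.04 ± 0.18 (adjusted p = 0.988), and PLP5 was not well above background in either sample.

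Under OPDA in Mpcoi1-2 heat shock and chaperone genes rose for 53 of 138 and fell for 4 (60 and 8 adjusted over the list alone; mean 1.13, median 0.31; adjusted p = 3.02e-14, and adjusted p = 0.00502 with an estimated correlation). Proteasome and ubiquitin genes rose for 41 of 260 and fell for 4 (43 and 4 adjusted over the list alone; adjusted p = 0.0134, and adjusted p = 0.584 with an estimated correlation), with the UFD1 family gene Mapoly0005s0132 at 8.66-fold and BRIZ1 Mapoly0007s0291 at 5.28-fold. Glutathione and redox genes rose for 22 of 102 and fell for 2 (22 and 4 adjusted over the list alone; adjusted p = 0.0270, and adjusted p = 0.322 with an estimated correlation). The photosynthesis list passed downward (mean -0.08; adjusted p = 0.0191, and adjusted p = 0.322 with an estimated correlation) with 5 genes higher and 6 lower of 118 (also adjusted over the list alone), and its gene with the largest named rise was ELIP2 Mapoly0047s0106, an early light-induced protein that binds pigment under stress, at 26.1-fold. Histone genes fell for 2 of 10 (4 adjusted over the list alone; adjusted p = 0.0462, and adjusted p = 0.386 with an estimated correlation).

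In this comparison 1211 genes were higher and 702 lower (53.2% higher with the values deposited as a series matrix, in place of 63.3%), and 2853 passed with slide 3 alone (1717 higher). Without replicate 1 or 2 of this comparison 988 and 1123 genes passed. The photosynthesis call was lost without replicate 1 (adjusted p = 0.347, 0.00323 to 0.347 over its settings), that of glutathione without replicate 2 (adjusted p = 0.0856, 0.00884 to 0.0947), within slide 3 (0.0567), without background subtraction (0.0947) and with scaling (0.0504). That of histones was lost without replicate 2 (adjusted p = 0.213, 0.0173 to 0.213), within slide 3 and without replicate 3 of OPDA in Tak-2 (0.0556), of Mpcoi1-2 against Tak-1 (0.0505) or of wounding (0.0518).

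The difference of the responses to OPDA was tested for each gene as Tak-2 minus Mpcoi1-2. Of 760 genes that differed, 293 had the higher log2 ratio in Tak-2 and 467 in Mpcoi1-2. Heat shock and chaperone genes differed for 35 of 138, 34 of them higher in Mpcoi1-2 (41 and 40 adjusted over the list alone; mean -0.66; adjusted p = 1.68e-09, and adjusted p = 0.0232 with an estimated correlation). Of 69 phenylpropanoid and flavonoid genes 15 were higher in Tak-2 and 1 in Mpcoi1-2 (19 and 2 adjusted over the list alone; adjusted p = 2.13e-05, and adjusted p = 0.376 with an estimated correlation). Among genes that differed were PLP5 Mapoly0106s0022 (3.01 ± 0.33), a terpenoid cyclase, Mapoly0108s0025 (2.75 ± 0.32), and the polyketide cyclase-like Mapoly0021s0121 (2.61 ± 0.42), all higher in Tak-2, and ELIP2 (-3.52 ± 0.36) and HSP20-like Mapoly0076s0006 (-5.52 ± 0.37). MpJAZ (Mapoly0097s0021) differed by 0.96 ± 0.23, a call lost without replicate 1 of OPDA in Tak-2 (0.76) and without replicate 1 or 2 of OPDA in Mpcoi1-2 (1.22 and 0.72). The MpJAZ call was also lost without background subtraction (0.47), with an offset of 10 (0.95), scaling (0.74) and the brightest probe (1.01). The replicate block (0.89), slide as a random block (0.96) and the 5 arrays alone (0.999) ended it too. The lines differ in sex and slide as well as in MpCOI1, so that these cannot be told apart here, and 0 genes passed with only the 5 arrays (1265 at an unadjusted p under 0.05). Without replicates 1 and 2 of OPDA in Mpcoi1-2 266 and 415 genes passed. Without that replicate 1 the phenylpropanoid call was lost (adjusted p = 0.0752, 9.77e-09 to 0.0752 over its settings), and without replicate 3 of OPDA in Tak-2 the median over all genes shifted to -0.12.

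**Figure D3:**
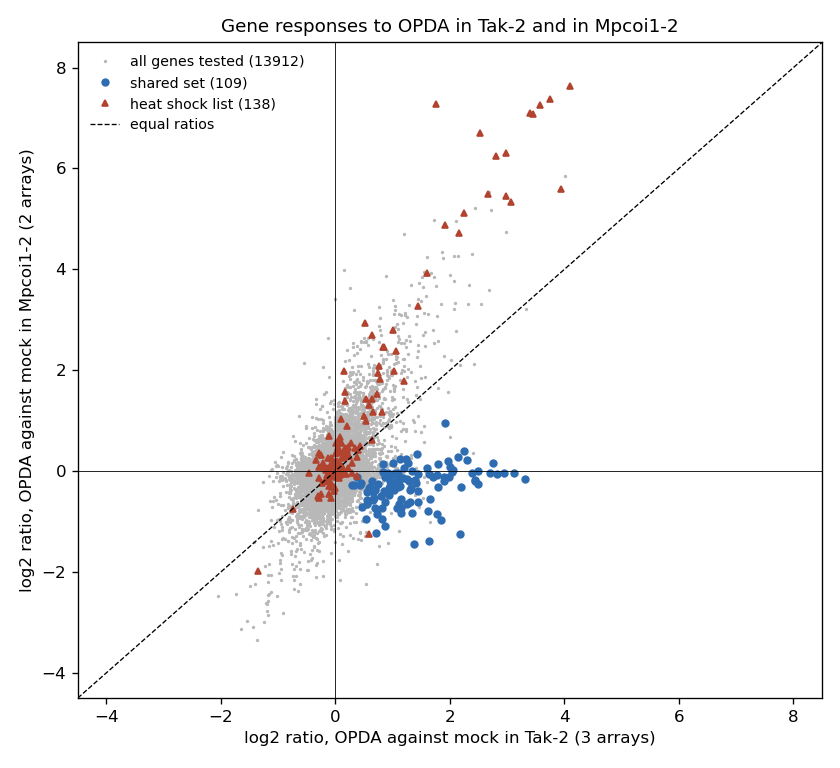
Log2 ratio under OPDA in Tak-2 (horizontal) against that in Mpcoi1-2 (vertical) for every tested gene, with the 138 heat shock genes and the 109 genes of the shared set marked and a line of equal ratios. The heat shock list has a mean of 0.48 in Tak-2 and 1.13 in Mpcoi1-2.

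Mpcoi1-1 was compared with Tak-2, both given OPDA, to ask which genes depend on the receptor in the female line. MpCOI1 itself, Mapoly0025s0025, had a log2 ratio of -0.58 ± 0.29 (adjusted p = 0.233) and was well above background on 1 of 3 mutant and 2 of 3 wild-type samples. The files do not place its 2 probes relative to the lesion, so the value checks nothing. MpJAZ was 5.07-fold lower in the mutant (-2.34 ± 0.15, adjusted p = 7.14e-08). The most reduced annotated genes were PLP5 Mapoly0106s0023 (37.9-fold, -5.24 ± 0.40, above background on 1 of 3 mutant samples), the CYP90A-like P450 Mapoly0033s0061 (36.1-fold, -5.17 ± 0.26) and the lipoxygenase Mapoly0106s0031 (35.3-fold, -5.14 ± 0.35, on 1 of 3). The polyketide cyclase-like Mapoly0021s0121 was 34.2-fold lower and CYP704B1 Mapoly0037s0114 33.5-fold (-5.06 ± 0.13, adjusted p = 1.69e-11). PAL1 Mapoly0070s0066, at the entry of phenylpropanoid synthesis, was 29.6-fold lower, the TT8-like bHLH Mapoly0028s0058 23.5-fold and GH3 Mapoly0053s0073, of a family that joins amino acids to hormones, 22.9-fold. Higher in the mutant were the kelch-repeat gene Mapoly0004s0111 (6.81-fold, 2.77 ± 0.27), POLGAMMA1 Mapoly0039s0093, an organelle DNA polymerase (5.93-fold, 2.57 ± 0.14), a calmodulin-binding gene, Mapoly0126s0010 (5.28-fold, 2.40 ± 0.12), and choline kinase Mapoly0005s0142 (3.68-fold, 1.88 ± 0.13).

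In Mpcoi1-1 against Tak-2, 14 lists passed camera and none of them kept the call with an estimated correlation. Peroxidases fell for 74 of 187 and rose for 4 (87 and 7 adjusted over the list alone; adjusted p = 1.21e-11, and adjusted p = 0.154 with an estimated correlation). Phenylpropanoid and flavonoid genes fell for 30 of 69 with 2 higher (the same adjusted over the list alone; mean -0.88; adjusted p = 4.61e-09, and adjusted p = 0.118 with an estimated correlation). Jasmonate and oxylipin biosynthesis genes fell for 12 of 32 and rose for 3 (14 and 3 adjusted over the list alone; mean -0.83; adjusted p = 0.000130, and adjusted p = 0.118 with an estimated correlation), with the acyl-CoA oxidase ACX3 Mapoly0007s0119 lower by -3.41 ± 0.14 and allene oxide cyclase AOC3 Mapoly0057s0049, the step that forms OPDA, at 8.48-fold. Cytochrome P450 genes fell for 29 of 132 (33 adjusted over the list alone; adjusted p = 0.000111, and adjusted p = 0.145 with an estimated correlation) and rose for 2. Defence genes fell for 63 of 208 with 15 higher (66 and 18 adjusted over the list alone; adjusted p = 0.000655, and adjusted p = 0.283 with an estimated correlation). PR5 Mapoly0097s0013, a thaumatin-like defence protein, was at least 10.8-fold lower. "At least" marks a fold taken against the background level because no array of a group was well above it. The bHLH, WRKY, terpene synthase and auxin lists passed downward with 12 of 36, 5 of 12, 3 of 8 and 8 of 34 genes lower and 2, 0, 0 and 2 higher (13, 6, 3 and 11 lower adjusted over the list alone; adjusted p = 0.00584, 0.0209, 0.0244 and 0.0341, and adjusted p = 0.201, 0.136, 0.118 and 0.357 with an estimated correlation). Heat shock, photosynthesis and ribosomal protein genes passed upward with 15 of 138, 13 of 118 and 13 of 189 higher and 6, 2 and 1 lower (16, 13 and 10 higher adjusted over the list alone; adjusted p = 0.00116, 0.00255 and 0.0127, and adjusted p = 0.118, 0.118 and 0.312 with an estimated correlation). The chlorophyll list with 1 of 8 and the glutathione list with 10 of 102 higher and 4 lower passed upward too (3 and 13 adjusted over the list alone; adjusted p = 0.00552 and 0.0108, and adjusted p = 0.118 and 0.125 with an estimated correlation).

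Of the 1983 genes 704 were higher and 1279 lower (35.5% higher; 47.4% with the scanner software's processed signals and 54.4% with the series matrix), 392 passed with the 3 arrays alone, 1029 within slide 1 (2 arrays, 312 higher), 644 within slide 2 (1 array, with the spread taken from the wounding arrays, 53 higher) and 1244 without replicate 3. Within slide 1 the terpene, auxin, bHLH and ribosomal lists no longer passed. Their means there were -0.77, -0.32, -0.44 and 0.06 (-0.77, -0.33, -0.47 and 0.06 in the main fit). Within slide 2 the terpene, auxin, WRKY, photosynthesis, chlorophyll and glutathione lists did not, but its 1 array is no test of how stable these calls are. The auxin call was also lost without replicate 2 (adjusted p = 0.0882, 0.0144 to 0.323 over its settings) or without replicate 1 of OPDA in Mpcoi1-2 (0.0528), and the ribosomal call without replicate 1 (adjusted p = 0.127, 0.000592 to 0.158).

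The male mutant Mpcoi1-2 was compared with Tak-1, both given OPDA, to ask the same of the second allele. MpCOI1 (Mapoly0025s0025) had a log2 ratio of -0.46 ± 0.29 (adjusted p = 0.631, 0.000206 to 0.960 over its settings), from probes of unknown place relative to the lesion. It passed the threshold without background subtraction (-0.59), with scaling (-0.77), with the 3 arrays alone (-0.56) and within slide 3 (-0.56). MpJAZ was 5.09-fold lower (-2.35 ± 0.15, adjusted p = 1.63e-07). PLP5 Mapoly0106s0023 was 116-fold lower (-6.85 ± 0.40), the TT8-like bHLH 52.6-fold (-5.72 ± 0.28), the CYP90A-like P450 39.9-fold (-5.32 ± 0.26), the lipoxygenase Mapoly0106s0031 27.4-fold (-4.77 ± 0.35) and GH3 19.9-fold (-4.32 ± 0.17, adjusted p = 9.36e-09). On the arrays of OPDA in Mpcoi1-2, this PLP5 gene and the TT8-like bHLH were not well above background with OPDA. The size of their folds is therefore uncertain. A GDSL lipase, Mapoly0016s0185, was 18.4-fold and chalcone synthase Mapoly0041s0118, which starts flavonoid synthesis, 15.5-fold lower. Higher in the mutant were ENODL14 Mapoly0130s0040, an early nodulin-like protein (3.00-fold, 1.58 ± 0.22), a dirigent-like gene, Mapoly0016s0001 (2.93-fold, 1.55 ± 0.15), and the sucrose transporter SUC4 Mapoly0009s0099 (2.62-fold, 1.39 ± 0.25).

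In Mpcoi1-2 against Tak-1 jasmonate and oxylipin biosynthesis genes fell for 11 of 32 and rose for 0 (15 and 3 adjusted over the list alone; mean -0.77; adjusted p = 4.86e-10, and adjusted p = 0.0484 with an estimated correlation), with ACX3 at 7.40-fold and AOC3 at 7.10-fold. Phenylpropanoid and flavonoid genes fell for 21 of 69 and rose for 1 (23 and 2 adjusted over the list alone; adjusted p = 2.10e-12, and adjusted p = 0.0664 with an estimated correlation). Peroxidases fell for 32 of 187, defence genes for 33 of 208 and P450 genes for 20 of 132, and 1, 5 and 2 rose (63, 52 and 27 lower adjusted over the list alone; adjusted p = 9.65e-13, 1.62e-06 and 0.000334, and adjusted p = 0.215, 0.215 and 0.215 with an estimated correlation). The bHLH and WRKY lists passed downward with 7 of 36 and 1 of 12 lower (7 and 5 adjusted over the list alone; adjusted p = 0.0173 and 0.0236, and adjusted p = 0.240 and 0.215 with an estimated correlation); the bHLH median was -0.00. Histone genes rose for 3 of 10 (6 adjusted over the list alone; adjusted p = 0.000287, and adjusted p = 0.101 with an estimated correlation). The ribosomal list passed upward with 0 genes called, and the heat shock list with 0 genes higher and 3 lower (0 and 2 adjusted over the list alone), at a mean of 0.06 and 0.09 (adjusted p = 0.0236 each, and adjusted p = 0.410 and 0.228 with an estimated correlation).

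Of the 815 genes 151 were higher and 664 lower. The share of higher genes, 18.5%, was 32.5% without background subtraction, 34.8% with scaling between arrays and 32.8% with the series matrix. Within slide 3 1336 genes passed (325 higher), and 1745 did with the 3 arrays alone, and 487, 465 and 471 without replicates 1, 2 and 3. The ribosomal call was lost without replicate 1 or 2 (adjusted p = 0.119 and 0.0667, 0.00125 to 0.119 over its settings), that of heat shock without 2 or 3 (adjusted p = 0.192 and 0.0591, 0.00153 to 0.192). That of WRKY was lost without replicate 3 (adjusted p = 0.0890, 0.0169 to 0.0903) and that of bHLH within slide 3.

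The effects of the mutant alleles were compared as Mpcoi1-1 minus Mpcoi1-2, each against its own wild type. CYP704B1 Mapoly0037s0114, of a P450 family that hydroxylates fatty acids for spore walls, differed most (-5.37 ± 0.17, adjusted p = 7.14e-10), lower in Mpcoi1-1, as was FBW2 Mapoly0058s0120 (-2.52 ± 0.14), an F-box gene. POLGAMMA1 (2.48 ± 0.19), choline kinase (1.98 ± 0.19, a call lost with the brightest probe) and the receptor-like kinase Mapoly0020s0097 (1.91 ± 0.16) were higher in Mpcoi1-1. MpJAZ (Mapoly0097s0021) had a difference of 0.01 ± 0.21 (adjusted p = 0.996, 0.000263 to 1.00 over its settings), but passed upward without background subtraction (1.15) and with scaling (1.78). In all 258 genes differed, 113 of them higher in Mpcoi1-1 (43.8%; 70.1% without background subtraction and 71.1% with scaling). Of the genes that differed from wild type, 615 differed in both mutants the same way (541 lower, 74 higher), where independence would give 68.7 and simulated unchanged samples of the same number of calls gave 91.4. The count of 258 was 133 without replicate 3 of Mpcoi1-1, 110, 153 and 122 without replicates 1, 2 and 3 of Mpcoi1-2, 158 with slide as a random block and 75 with the 6 arrays alone. The jasmonate biosynthesis list had a mean of -0.06 (adjusted p = 0.934) and passed upward with scaling (0.56, adjusted p = 2.20e-05). Allele, sex and slide differ together.

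Wounding with tweezers was compared with no wounding in 21-day Tak-1 thalli, to ask which genes respond to damage. PLP5 Mapoly0106s0023 rose 65.8-fold (6.04 ± 0.40, adjusted p = 6.84e-08, above background on 2 of 3 unwounded samples), VEP1 61.3-fold (5.94 ± 0.41), the CYP90A-like P450 53.3-fold (5.74 ± 0.26) and Rap2.6L Mapoly0166s0010, an ERF transcription factor, 53.0-fold (5.73 ± 0.26, on 2 of 3). OPR1 rose 25.1-fold (4.65 ± 0.38), the TT8-like bHLH 28.1-fold (4.81 ± 0.28), GSTU8 at least 25.0-fold, and MpJAZ 4.16-fold (2.06 ± 0.15, adjusted p = 1.41e-07). An aspartyl protease, Mapoly0185s0031, fell 7.88-fold (-2.98 ± 0.20, on 2 of 3 wounded samples), CYP709B1 Mapoly0024s0025 6.30-fold (-2.66 ± 0.21), a rhamnogalacturonate lyase of pectin breakdown, Mapoly0026s0014, 5.85-fold (-2.55 ± 0.14) and metacaspase 4 Mapoly0013s0025 5.34-fold (-2.42 ± 0.18).

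Under wounding 11 of 12 WRKY genes rose (12 adjusted over the list alone; mean 1.64; adjusted p = 1.40e-11, and adjusted p = 0.00197 with an estimated correlation), WRKY57 Mapoly0057s0012 by 9.52-fold. Jasmonate and oxylipin biosynthesis genes rose for 18 of 32 and fell for 4 (19 and 6 adjusted over the list alone; mean 0.88; adjusted p = 2.59e-05, and adjusted p = 0.127 with an estimated correlation), ACX3 by 13.5-fold and the desaturase FAD7 Mapoly0058s0050 by 2.92-fold. Peroxidases fell for 104 of 187 and rose for 20 (110 and 20 adjusted over the list alone; adjusted p = 1.96e-12, and adjusted p = 0.170 with an estimated correlation). Cell wall expansion genes fell for 39 of 101 and rose for 9 (44 and 9 adjusted over the list alone; adjusted p = 2.83e-06, and adjusted p = 0.147 with an estimated correlation): expansin A9 Mapoly0118s0015 fell 4.04-fold, while the xyloglucan-modifying XTH5 Mapoly0094s0049 and XTH6 Mapoly0094s0050 rose 13.6-fold and 7.58-fold. Photosynthesis genes fell for 24 of 118 and rose for 4 (the same adjusted over the list alone; adjusted p = 0.000596, and adjusted p = 0.127 with an estimated correlation). Heat shock, proteasome and ABC transporter genes rose for 39 of 138, 54 of 260 and 6 of 15 and fell for 7, 16 and 1 (40, 55 and 6 adjusted over the list alone; adjusted p = 0.0247, 0.0283 and 0.0328, and adjusted p = 0.224, 0.487 and 0.170 with an estimated correlation). Of 27 AP2/ERF genes 8 rose and 3 fell (9 and 3 adjusted over the list alone), and of 29 reference genes 4 rose and 8 fell (4 and 10 adjusted over the list alone), each with a list adjusted p = 0.0535.

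Of the 3318 genes 1876 were higher and 1442 lower (56.5% higher; 42.3% with the series matrix), 2673 passed within slide 2 (1604 higher) and 1984 with the 3 arrays alone. The calls of the heat shock, proteasome and ABC transporter lists were lost without replicate 3 (adjusted p = 0.0557 each, up to 0.0557, 0.184 and 0.0595 over their settings), that of the proteasome without replicate 1 (0.0684) and that of ABC transporters within slide 2.

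The AtCOI1 line in Mpcoi1-1, given 0.5 µM coronatine, a bacterial mimic of jasmonoyl-isoleucine, was compared with mock-treated Mpcoi1-1, to ask what the Arabidopsis receptor with its ligand changes. Genotype and treatment differ together. MpCOI1 had a log2 ratio of 0.06 ± 0.29 (adjusted p = 1.00) and MpJAZ rose 4.64-fold (2.21 ± 0.15, adjusted p = 3.20e-07). The TT8-like bHLH rose 44.9-fold (5.49 ± 0.28), the CYP90A-like P450 40.3-fold (5.33 ± 0.26), the polyketide cyclase-like gene 26.6-fold (4.74 ± 0.27), the GDSL lipase Mapoly0016s0185 24.0-fold (4.58 ± 0.25) and GH3 14.6-fold (3.87 ± 0.17). PLP5 Mapoly0106s0023 rose at least 40.8-fold and the terpenoid cyclase Mapoly0108s0025 at least 20.7-fold. The germin-like GLP10 Mapoly2349s0001 fell 3.08-fold (-1.62 ± 0.17), MYB16 Mapoly0096s0058, of a family that shapes epidermal cells, 2.54-fold (-1.35 ± 0.15) and the auxin synthesis gene YUC2 Mapoly0063s0040 1.88-fold (-0.91 ± 0.15).

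In the coronatine comparison 6 of 32 jasmonate and oxylipin biosynthesis genes rose and 0 fell (10 and 0 adjusted over the list alone; mean 0.55; adjusted p = 4.04e-09, and adjusted p = 0.0316 with an estimated correlation): ACX3 rose 5.02-fold, allene oxide synthase AOS Mapoly0185s0014 4.70-fold, LOX3 Mapoly0191s0014 4.60-fold and AOC3 4.04-fold. Histone genes fell for 5 of 10 (5 adjusted over the list alone; mean -0.37; adjusted p = 4.04e-09, and adjusted p = 0.0167 with an estimated correlation). Phenylpropanoid and flavonoid genes rose for 15 of 69, bHLH genes for 8 of 36 and P450 genes for 12 of 132 with 1 lower (19, 9 and 12 adjusted over the list alone; adjusted p = 1.38e-06, 0.000183 and 0.000183, and adjusted p = 0.155, 0.155 and 0.263 with an estimated correlation). The cyclin list passed downward with 0 genes called and a mean of -0.06 (adjusted p = 0.0258, and adjusted p = 0.568 with an estimated correlation), and 2 of 8 terpene synthase genes rose (2 adjusted over the list alone; adjusted p = 0.0458, and adjusted p = 0.155 with an estimated correlation). Of 138 heat shock genes 3 rose (2 adjusted over the list alone), with a list mean of 0.04 and a camera sign of down (adjusted p = 0.935). Of the 400 genes higher under coronatine, 303 also rose under wounding, and 296 were lower in both mutants.

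Of the 460 genes 400 were higher and 60 lower. The share of higher genes, 87.0%, was 72.1% without background subtraction and 76.4% with scaling. Within slide 3 658 genes passed (530 higher), and without replicate 1 294 did. The cyclin mean was 0.01 without replicate 3 (adjusted p = 0.205, 0.00337 to 0.205 over its settings) and its call was also lost without replicate 2 (0.0909). The terpene call was lost within slide 3 (adjusted p = 0.232, 0.0167 to 0.232 over its settings) and without replicate 3 (0.205). It was also lost without replicate 1 or 3 of OPDA in Tak-2 (0.0540 and 0.0877), any replicate of Mpcoi1-1 against Tak-2 (0.0523 to 0.0718), replicate 2 of Mpcoi1-2 against Tak-1 (0.0568) or replicate 2 of wounding (0.0559).

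**Figure D4:**
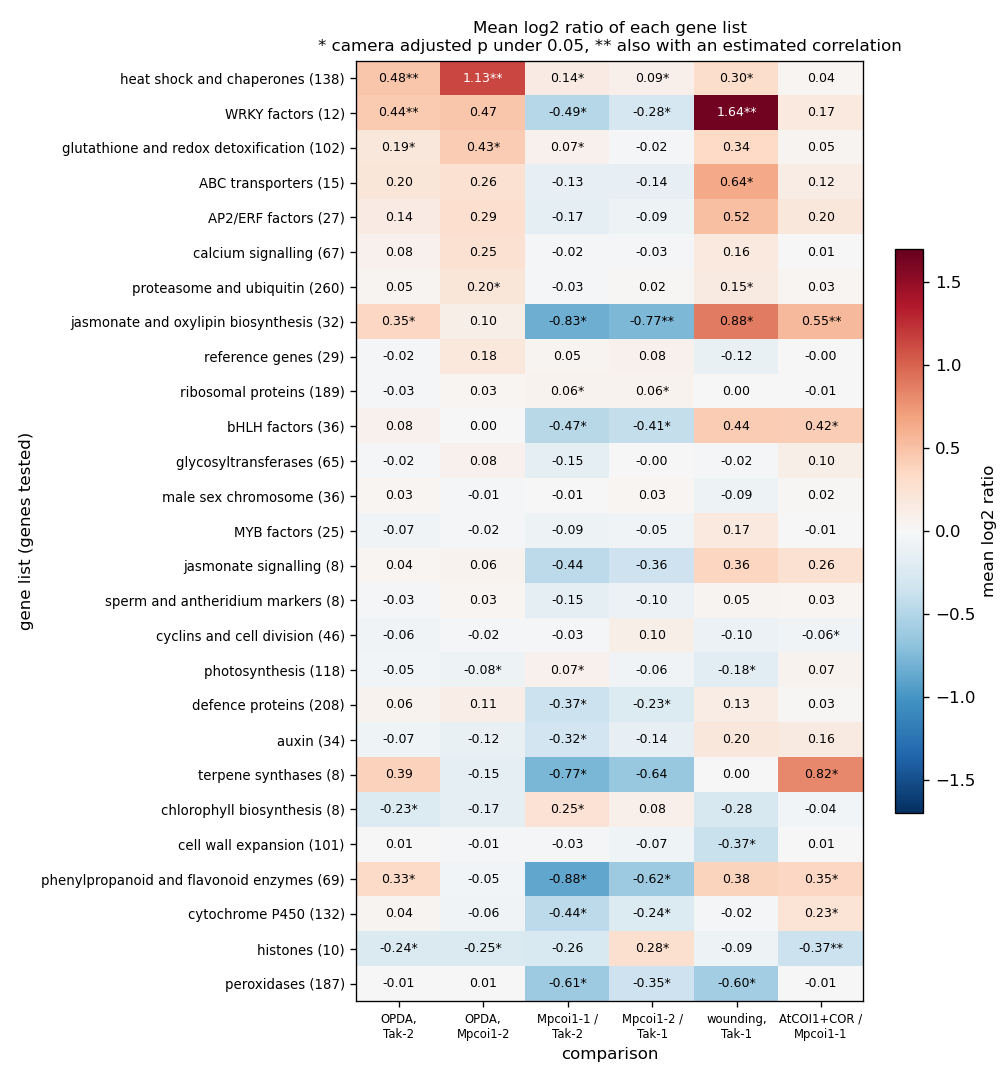
Mean log2 ratio of each of 27 gene lists (rows) in the 6 comparisons (columns), with a mark where camera passed and a double mark where it also passed with an estimated correlation. The jasmonate biosynthesis list runs from -0.83 in Mpcoi1-1 against Tak-2 to 0.88 under wounding.

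The genes changed by OPDA in Tak-2 were set against those of each other comparison. With OPDA in Mpcoi1-2, 675 genes changed the same way (459 higher, 216 lower), where independence would give 85.3 and simulated unchanged samples with as many calls gave 108. With wounding 837 did (614 higher; 142 and 180), and with the coronatine comparison 229 (211 higher; 23.3 and 38.5). Of genes also changed in the mutants, those that moved the opposite way were 386 in Mpcoi1-1 (315 of them higher under OPDA; 89.0 by independence, 106 by simulation with separate samples and 380 where the wild type OPDA sample was the same extract) and 290 in Mpcoi1-2 (261 higher under OPDA; 40.1, 47.7 and 48.6). Those that moved the same way were 144 in Mpcoi1-1 (111 higher; 74.5, 118 and 11.8) and 22 in Mpcoi1-2 (14 higher; 27.1, 57.2 and 59.8). The labels do not say whether the Tak-2 OPDA extracts were shared between comparisons. Across genes, which are not independent replicates, log2 ratios of OPDA in Tak-2 correlated at r = 0.58 with OPDA in Mpcoi1-2 and with wounding, 0.41 with coronatine, -0.31 with Mpcoi1-1 and -0.44 with Mpcoi1-2, with covariances of 0.121, 0.132, 0.051, -0.058 and -0.067. For Mpcoi1-1 the simulated values with a shared extract were r = -0.46 and a covariance of -0.015, so that part of that overlap may come from shared extracts. That simulation placed all of the spread in the extracts and none in the arrays, which gives sharing its largest effect. Without replicate 1 of OPDA in Tak-2 the first 5 of these counts, in the order given, were 352, 399, 126, 186 and 156, and with the arrays of each comparison alone 0 (limma; 1239 genes for OPDA in Tak-2 at an unadjusted p under 0.05).

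Among the 749 genes higher under OPDA in Tak-2, 136 responded more in Tak-2 than in Mpcoi1-2 by the test of the difference and 206 responded more in Mpcoi1-2. A set of 109 genes rose under OPDA in Tak-2, wounding and coronatine, was lower in both mutants and responded more to OPDA in Tak-2 than in Mpcoi1-2; 72 of them carry a description. It holds MpJAZ (whose call of the difference was lost in several settings, as given above), PLP5 Mapoly0106s0023, the lipoxygenase Mapoly0106s0031, LOX3 and GH3. It also holds 4 chalcone synthase genes, PAL1 Mapoly0070s0068 and PAL2 Mapoly0070s0069, 4 MtN21-like transporters, and the tryptophan synthesis genes TRP1 Mapoly0027s0124 (1.09 under OPDA in Tak-2) and TRP4 Mapoly0037s0136 (1.20). Genes that rose under OPDA in both lines numbered 459, of which 380 also rose under wounding.

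OPDA in Tak-2 was compared with wounding in Tak-1, which differ in sex, age and slide (the time after wounding is not given, so it may differ from the 2 h of OPDA), and with coronatine in the AtCOI1 line, which differs in compound, dose and genotype. Against wounding 1296 genes differed, 419 with the higher log2 ratio under OPDA (32.3%; 44.5% with the series matrix). Peroxidases were higher under OPDA for 69 of 187 and lower for 6 (89 and 12 adjusted over the list alone; adjusted p = 3.94e-17, and adjusted p = 0.117 with an estimated correlation), and cell wall expansion genes for 29 of 101 and 6 (37 and 9 adjusted over the list alone; adjusted p = 7.84e-08, and adjusted p = 0.117 with an estimated correlation). WRKY genes were lower under OPDA for 8 of 12 (8 adjusted over the list alone; mean -1.20; adjusted p = 1.56e-10, and adjusted p = 0.00294 with an estimated correlation), and jasmonate biosynthesis genes for 12 of 32 with 1 higher (15 and 3 adjusted over the list alone; adjusted p = 0.00257, and adjusted p = 0.170 with an estimated correlation). With slide as a fixed block 526 genes differed (105 higher under OPDA), and the WRKY mean was -1.35 and the cell wall mean 0.18. The peroxidase mean was 0.11 with the call lost (adjusted p = 0.0618, 1.08e-19 to 0.0618 over its settings), as were those of jasmonate biosynthesis (-0.41) and MpJAZ (Mapoly0097s0021, -1.08). With the 6 arrays alone 460 genes differed. The photosynthesis list was higher under OPDA with 4 of 118 genes called (0 adjusted over the list alone), the reference genes with 1 of 29 (0 adjusted over the list alone) and terpene synthases with 3 of 8 (4 adjusted over the list alone), and ABC transporters were lower with 4 of 15 (5 adjusted over the list alone). Their adjusted p = 0.00257, 0.0413, 0.0413 and 0.0413, and adjusted p = 0.117, 0.117, 0.117 and 0.170 with an estimated correlation. With slide as a fixed block their means were 0.08, 0.06, 0.39 and -0.42 (0.13, 0.11, 0.39 and -0.44 in the main fit). All 4 calls were lost there (adjusted p = 0.0988, 0.131, 0.131 and 0.299, the highest of their settings). The last 3 were also lost (adjusted p of 0.0505 to 0.0793) on leaving out single arrays. For ABC transporters these were replicate 1 of OPDA in Tak-2 or of Mpcoi1-1, replicate 2 or 3 of wounding, or replicate 3 of coronatine. For reference genes they were replicate 1 or 2 of OPDA in Tak-2, replicate 1 of Mpcoi1-1 or replicate 2 or 3 of wounding, and for terpene synthases replicate 3 of OPDA in Tak-2, of wounding or of coronatine, or replicate 1 of Mpcoi1-1.

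Against coronatine 386 genes differed, 215 with the higher log2 ratio under OPDA (55.7%; 33.0% without background subtraction and 33.4% with scaling). Heat shock genes were higher under OPDA for 26 of 138 and lower for 2 (32 and 4 adjusted over the list alone; mean 0.44; adjusted p = 1.96e-09, and adjusted p = 0.0238 with an estimated correlation), and GSTF10 was higher by 3.28 ± 0.38. The TT8-like bHLH (-4.06 ± 0.39), the CYP90A-like P450 (-3.44 ± 0.36) and CYP94D2 Mapoly0023s0003 (-2.59 ± 0.21) were lower under OPDA. The log2 ratio of MpJAZ over its control was lower under OPDA than under wounding by -1.14 ± 0.21 (adjusted p = 0.00262). Against coronatine it was lower by -1.30 ± 0.21 (adjusted p = 0.00350). These are ratios over different controls, not levels of MpJAZ. At its brighter probe the log2 level of the controls was 9.93 to 10.3 in mock-treated Tak-2. It was 8.51 to 8.97 in unwounded Tak-1 and 7.84 to 8.10 in mock-treated Mpcoi1-1. With the 6 arrays alone 0 genes differed from coronatine in limma (1097 at an unadjusted p under 0.05). Without replicates 1, 2 and 3 of OPDA in Tak-2 231, 186 and 842 did, and without replicates 1 and 2 of coronatine 178 and 224. Without replicate 3 of OPDA in Tak-2 the median over all genes was -0.12. Of 36 bHLH genes 3 were lower under OPDA (5 adjusted over the list alone; adjusted p = 0.0230, and adjusted p = 0.456 with an estimated correlation) and of 12 WRKY genes 1 was higher (adjusted p = 0.0230, and adjusted p = 0.280 with an estimated correlation). The bHLH call was lost without replicate 2 or 3 of OPDA in Tak-2 or replicate 1 or 3 of coronatine (adjusted p of 0.0534 to 0.0935, 0.00109 to 0.0935 over its settings), and the WRKY call without replicate 1 of OPDA in Tak-2 or replicate 1 or 3 of coronatine (0.0556 to 0.138, 0.00895 to 0.317). The jasmonate biosynthesis list had a mean of -0.20 (adjusted p = 0.178) and passed downward without background subtraction (-0.28, adjusted p = 0.0165) and with scaling (-0.48, adjusted p = 0.00438). With slide as a random block 228 genes differed, and slide as a fixed block could not be fitted for this difference, since the OPDA and coronatine arrays share no slide.

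The 8 lists that passed camera in none of the 6 comparisons included the reference genes (list adjusted p of 0.0535 to 0.784) and AP2/ERF factors, of which 5 of 27 rose under OPDA in Tak-2, 3 under OPDA in Mpcoi1-2 and 8 under wounding (0.0535 to 0.630). Under wounding the reference genes passed downward without replicate 1 or 2 of OPDA in Mpcoi1-2 (adjusted p = 0.0497 in each), and AP2/ERF factors upward without background subtraction (0.0393) and with scaling (0.0412). Of 8 jasmonate signalling genes 2 rose and 1 fell under OPDA in Tak-2, and 2 rose under wounding (0.121 to 0.964). Calcium signalling genes rose for 10 of 67 and fell for 5 under OPDA in Mpcoi1-2, and rose for 11 and fell for 2 under wounding (0.284 to 0.857). Glycosyltransferases rose for 9 of 65 and fell for 3 under OPDA in Mpcoi1-2 (0.249 to 0.964), and MYB factors rose for 5 of 25 and fell for 1 under wounding (0.212 to 0.964). Of 8 sperm and antheridium markers 1 rose and 1 fell under wounding (0.439 to 0.964), and of 36 male sex chromosome genes 1 rose under OPDA in Mpcoi1-2 and 1 fell under wounding (0.249 to 0.847). In all, 71 of the 270 list tests, differences between comparisons included, passed, and 10 passed with an estimated correlation. With another background, offset, scaling or signal, 21 of the 71 calls were lost. They were glutathione and chlorophyll under OPDA in Tak-2, glutathione, photosynthesis and histones under OPDA in Mpcoi1-2, WRKY and auxin in Mpcoi1-1, and WRKY and bHLH in Mpcoi1-2. Others were ABC transporters, proteasome and heat shock under wounding and terpene synthases under coronatine. Among differences they were jasmonate biosynthesis for the OPDA responses, glutathione, peroxidases and phenylpropanoid genes for the alleles, ABC transporters, reference genes and terpene synthases for wounding, and WRKY for coronatine.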

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

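The tests of chance placement on scaffolds, of a line difference other than MpCOI1, of mock RNA in replicate 3 of OPDA in Tak-2 and of signal compression on slide 1 were chosen only after the result was seen. The same holds for the use of the heat shock values of the mutants against wild type and of the lower genes in that replicate 3.

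The responses to OPDA in Tak-2 and Mpcoi1-2 differed for 760 genes by the test of the difference. The largest differences with a description, taking 1 gene per description, were those of the MtN21-like transporter Mapoly0185s0009 (3.43), PLP5 Mapoly0106s0022 (3.01), chalcone synthase Mapoly0070s0064 (2.81), the terpenoid cyclase Mapoly0108s0025 (2.75) and the polyketide cyclase-like Mapoly0021s0121 (2.61), all higher in Tak-2. In the other direction were HSP20-like Mapoly0076s0006 (-5.52), HSP17.6A Mapoly0010s0141 (-4.18), peroxidase Mapoly0040s0117 (-3.84), ELIP2 Mapoly0047s0106 (-3.52) and the class II heat shock protein Mapoly0045s0084 (-3.44). MpJAZ differed by 0.96. Of these, Mapoly0185s0009, Mapoly0070s0064 and MpJAZ lost their call without replicate 1 of OPDA in Mpcoi1-2 (1.81, 1.84 and 1.22). MpJAZ lost it in other settings too, as given above. The list means were -0.66 for heat shock, 0.38 for phenylpropanoid and flavonoid enzymes, 0.25 for jasmonate biosynthesis (adjusted p = 0.0443, and adjusted p = 0.553 with an estimated correlation) and 0.10 for P450 genes (adjusted p = 0.0443, and adjusted p = 0.649 with an estimated correlation). The jasmonate biosynthesis call was lost without replicate 1 of OPDA in Tak-2 (adjusted p = 0.150) or of OPDA in Mpcoi1-2 (0.366), with a range of 0.00292 to 0.393 over its settings. The P450 call was lost without replicate 1 or 3 of OPDA in Tak-2 (0.0557 and 0.159) or replicate 1 or 2 of OPDA in Mpcoi1-2 (0.0771 and 0.0577), with a range of 0.0307 to 0.159.

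The effects of the mutant alleles differed for 258 genes. Higher in Mpcoi1-1 were POLGAMMA1 Mapoly0039s0093 (2.48), the kelch-repeat gene Mapoly0004s0111 (2.31), the kinase and phosphatase Mapoly0116s0039 (1.98), choline kinase Mapoly0005s0142 (1.98) and the receptor-like kinase Mapoly0020s0097 (1.91). Lower were CYP704B1 Mapoly0037s0114 (-5.37), peroxidase Mapoly0047s0007 (-2.73), FBW2 Mapoly0058s0120 (-2.52), the thaumatin-like Mapoly0097s0008 (-2.44) and PR5 Mapoly0097s0013 (-2.30). PR5 was not well above background in any of the mutant samples compared here (at least 10.8-fold and at least 2.15-fold lower than wild type), so its value is no measured difference of alleles. The peroxidase, the thaumatin-like gene and PR5 lost their call without background subtraction and with scaling, and the kelch-repeat gene and choline kinase with the brightest probe. List means were -0.53 for histones (adjusted p = 1.14e-05, and adjusted p = 0.0824 with an estimated correlation), 0.13 for photosynthesis (9.04e-05, and adjusted p = 0.0825 with an estimated correlation) and 0.0844 for glutathione genes (0.00704, and adjusted p = 0.162 with an estimated correlation). They were -0.26 for peroxidases (0.00704, and adjusted p = 0.934 with an estimated correlation) and -0.26 for phenylpropanoid genes (0.0239, and adjusted p = 0.885 with an estimated correlation). Without replicate 1 of Mpcoi1-1 the peroxidase and phenylpropanoid calls were lost (adjusted p = 0.645 and 0.211), as without replicate 2 of Mpcoi1-2 (0.196 and 0.193), and the phenylpropanoid call without replicate 2 of Mpcoi1-1 (0.0880) or replicate 1 of Mpcoi1-2 (0.0772). Over their settings the ranges were 2.96e-06 to 0.645 and 0.00108 to 0.633. Both means changed sign, to 0.0573 and 0.0494 without background subtraction and to 0.0965 and 0.303 with scaling (adjusted p = 0.217, 0.633, 0.220 and 0.00479). The glutathione call was lost in these settings too (adjusted p = 0.172 in each, 0.00594 to 0.172 over its settings).

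Heat shock genes responded more to OPDA in Mpcoi1-2 than in Tak-2: the mean over the 138 genes was 1.13 there and 0.48 in Tak-2, and 34 genes were lower and 1 higher in Tak-2 by the test of the difference. Replicate 3 of Tak-2 is excluded as the only cause, since without it the mean difference was -0.58 in place of -0.66 (median over all genes -0.12). It may contribute to the size. The 22 heat shock genes at least 2-fold higher in replicates 1 and 2 of Tak-2 had a median of 3.33 there and 0.89 in replicate 3. Compression of signal by the background of slide 1 is argued against only if the 2 alleles have effects of equal size. The slope of Mpcoi1-1 effects on slide 1 against Mpcoi1-2 effects on slide 3 was 0.96 (95% interval 0.92 to 0.99, 815 genes). That interval is over genes, which are not independent replicates. A larger Mpcoi1-1 effect compressed on slide 1 could give this slope too. A difference of the lines in sex, background or MpCOI1 may underlie it. Between lines of the same sex with OPDA in both, the mean was 0.09 in Mpcoi1-2 against Tak-1, where 0 genes were higher. In Mpcoi1-1 against Tak-2 it was 0.14, with more genes higher than lower. Over the 53 genes that rose under OPDA in Mpcoi1-2, the medians were 0.22 and 0.28. Tak-1 without OPDA was measured only in 21-day plants on the wounding arrays, so its response to OPDA is unknown and MpCOI1 stays open.

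Genes that differed in Mpcoi1-1 and in the difference of alleles but not in Mpcoi1-2 (163 genes) lay on shared scaffolds: 191 pairs shared 1, which was 1.88 times the mean of 10000 random draws (highest draw 184). Copies that share a description do not account for this among described genes: with 1 gene per description and scaffold (93 genes) the ratio was 2.58 (highest draw 2.49). Copies without a description, or with different ones, were not tested. A dye error is argued against by the dye-swapped replicate 2, whose median was 0.84 in the direction of the call, with 125 of 136 genes on that side. This replicate cannot decide on a slide error that does not turn with the dye. It lies on slide 1 like replicate 3, and Mpcoi1-2 lies on slide 3. A difference between the lines other than MpCOI1 may contribute, but this was not decided. The coronatine comparison, where both RNAs share the Mpcoi1-1 background, had a median of -0.0251 against the mutant effect over these genes. Over the 615 genes changed in both mutants it was 0.55. The choice of genes by their call in Mpcoi1-2 partly sets both medians. Across genes, which are not independent replicates, Mpcoi1-2 effects correlated with the coronatine comparison at r = -0.77, and both lie on slide 3. These values were found and tested on the same arrays.

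The third array of OPDA in Tak-2 departed from the other two: of 255 genes at least 2-fold higher in both others 244 were above 0 in it, but of 319 lower genes only 57 were below 0. Mock RNA mixed into the treated sample shrinks ratios toward 0 and does not turn them, so the lower genes argue against it as the only cause. Mixing beside another cause could not be told apart. The quartile ratio of the share of treated RNA was 3.24 (95% interval over genes, which are not independent replicates, 2.30 to 5.36). A ratio under 2 was predicted for mixing and one over 3 otherwise. That ratio covered only the 71 genes at least 4-fold higher in both others. A gene-specific dye effect on slide 1 could not be told apart either, with a slope of 0.39 (95% interval, again over genes, 0.36 to 0.41). No biological explanation was tested.

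For OPDA in Tak-2, Mpcoi1-1, Mpcoi1-2, wounding and coronatine the real assignment of the channels was 1 of 4, and for the 3 differences between comparisons of 3 arrays the real split was 1 of 10, too few for a share under 0.05. The real counts were 1147, 1983, 815, 3318 and 460, against a highest other of 591, 2, 0, 4 and 7. For the differences of alleles, of OPDA and wounding and of OPDA and coronatine they were 258, 1296 and 386, against 2, 97 and 56.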

How the results depend on the processing

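A dye effect per slide, the arrays of 1 slide only and slide as a fixed block were chosen only after the data were seen. Of 372 named values 360 were called; none of these changed direction under any alternative, 213 kept the call under every alternative that held them and 147 lost it under at least 1, 112 of them with only the arrays of a comparison and 53 with the 2-fold threshold. The filter on every array held 325 of the named values, single slides 102, 110 and 126, and slide as a fixed block 34. Of 71 list calls, 24 were lost on leaving out some array, 30 in some other setting with the fixed correlation and 61 with an estimated correlation. Of the 199 other list tests 22 passed on leaving out some array, 21 in some other setting (9 without background subtraction, 14 with scaling) and 0 with an estimated correlation. Among them were jasmonate biosynthesis between alleles (0.56 with scaling, adjusted p = 2.20e-05), and peroxidases under coronatine (-0.147, adjusted p = 5.19e-07) and in OPDA minus coronatine (0.147, adjusted p = 8.84e-05) without replicate 2 of coronatine. Signal over background limits the green channel of slides 1 and 2, with 21.2% to 42.6% of spots well above it. The counts below differ by over 1.5 times from the main ones, and the cause was not tested, except where fewer arrays or a stricter threshold make it so.

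Without background subtraction the counts were 542 for OPDA in Tak-2, 3656 for OPDA in Mpcoi1-2, 1247 and 2025 for Mpcoi1-1 and Mpcoi1-2 against wild type, 991 for coronatine, 2096 for the difference of OPDA responses and 595 for that of alleles. Overlaps with OPDA in Tak-2 were 400 (OPDA in Mpcoi1-2), 199 (Mpcoi1-1) and 466 (wounding). With scaling they were 555, 3146, 1082, 2174, 2150 (wounding), 867, 1738, 526 and 589 (OPDA minus wounding), with overlaps of 411, 158 and 398. With array weights they were 2911 (OPDA in Tak-2), 2190 (Mpcoi1-2), 898 (coronatine), 1562 and 410 (differences of OPDA responses and alleles) and 1641 (OPDA minus coronatine), with overlaps of 1013, 623 (Mpcoi1-2) and 395 (coronatine). With only the arrays of a comparison they were 0 for OPDA in Tak-2 (limma, 1239 at an unadjusted p under 0.05), 392 for Mpcoi1-1, 1745 for Mpcoi1-2, 1984 for wounding, 0 (1265), 75, 460 and 0 (1097) for the 4 differences, and 0 for all 5 overlaps.

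With at least 2-fold they were 299, 768, 587, 307, 1048, 219, 467, 142, 651 and 226 in the order of the text (6 comparisons, then differences of OPDA responses, alleles, wounding and coronatine), and overlaps 173, 122, 105, 228 and 93. Slide as a random block gave 158 for the alleles and 228 for OPDA minus coronatine. Within slides the counts were 323 (OPDA in Tak-2), 1029 and 644 (Mpcoi1-1, 2 arrays on slide 1 and 1 array on slide 2, its spread from the wounding arrays) and 1336 (Mpcoi1-2), and with slide as a fixed block 526 (OPDA minus wounding). With an estimated correlation 10 lists passed. The other settings moved no count by over 1.5 times. In processed signals the median of all genes was -0.10 for OPDA in Tak-2.

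With 1 array left out, counts ran from 522 to 1992 (OPDA in Tak-2), 988 to 2136 (OPDA in Mpcoi1-2), 1244 to 2328 (Mpcoi1-1), 465 to 929 (Mpcoi1-2), 2465 to 3681 (wounding) and 294 to 524 (coronatine), and from 266 to 935, 110 to 369, 894 to 1576 and 178 to 842 for the 4 differences. Overlaps ran from 352 to 755, 186 to 449, 156 to 328, 399 to 1005 and 126 to 278, lowest without replicate 1 and highest without replicate 3 of OPDA in Tak-2, and lists from 64 to 76. The arrays that moved a count by over 1.5 times were replicates 1, 2 and 3 of OPDA in Tak-2 (522, 757, 1992; OPDA minus coronatine 231, 186, 842), 1 and 2 of OPDA in Mpcoi1-2 (988, 1123; difference 266, 415), 3 of Mpcoi1-1 (1244; alleles 133), 1, 2 and 3 of Mpcoi1-2 (487, 465, 471; alleles 110, 153, 122) and 1 and 2 of coronatine (294 without 1; OPDA minus coronatine 178, 224).

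Values that changed sign were those of uncalled genes, MpCOI1 (Mapoly0025s0025) and MpJAZ (Mapoly0097s0021), and list means. MpCOI1 under coronatine was -0.0327 without background subtraction, -0.0453 without a dye term, -0.0453 with its own arrays, and -0.0433 with a dye effect per slide or slide 3 only. Its difference of OPDA responses was 0.26 without background subtraction, 0.13 with offset 10, 0.0270 with scaling, 0.0322 with the series matrix, 0.00428 with the replicate block and 0.0812 with a dye effect per slide. Its difference of alleles was 0.47 (without background subtraction, past the threshold), 0.0155 (offset 10), 0.16 (processed signals) and 0.35 (scaling), its difference of OPDA and wounding -0.70 (processed signals) and -0.0886 (array weights), and its value in Mpcoi1-1 0.11 on slide 2 (n = 1). MpJAZ differed between alleles by -0.66 (processed signals) and -0.32 (brightest probe) and was 0.0181 under OPDA in Mpcoi1-2 with the replicate block. With 1 array left out, MpCOI1 ran from -0.0869 to 0.45 (coronatine), -0.41 to 0.22, -0.39 to 0.35 and -0.15 to 0.47 (differences of OPDA responses, alleles and wounding), MpJAZ from -0.29 to 0.20 (OPDA in Mpcoi1-2) and -0.11 to 0.10 (alleles). The cyclin mean under coronatine ran from -0.107 to 0.0135. Between alleles the peroxidase mean was 0.0573 without background subtraction and 0.0965 with scaling, and the phenylpropanoid mean 0.0494 and 0.303 (upward past the threshold); the glutathione mean in Mpcoi1-1 was -0.00739 on slide 2 (n = 1).

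Whether the replicate numbers pair the samples stays open: of 40 pairs of arrays with the same number 13 had deviations that correlated at over 0.1 (-0.556 to 0.496). A shared Tak-2 OPDA extract would give negative values, and replicates 1, 2 and 3 gave 0.413, -0.556 and -0.301. A shared Mpcoi1-2 OPDA extract would give positive values, and replicates 1 and 2 gave 0.093 and 0.496. Dye effects also enter these deviations. With the replicate number as a block the counts were 1031, 1788, 1759, 733, 3102, 434, 716, 198, 1185 and 333, and 70 lists passed.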

Other observations

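The values of the pair of genes without description, and the choice of genes from the shared set below, were picked only after the values were seen.

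The genes named here are from the set that rose with OPDA in Tak-2, wounding and coronatine and was lower in both mutants. IAMT1 Mapoly0092s0080, which methylates auxin, had log2 ratios of 2.19 under OPDA in Tak-2, -0.31 under OPDA in Mpcoi1-2, -3.64 and -3.65 in Mpcoi1-1 and Mpcoi1-2 against wild type, 2.95 under wounding and 2.78 under coronatine. For GH3 Mapoly0053s0073 these were 1.35, -0.83, -4.52, -4.32, 3.66 and 3.87. MGD1 Mapoly0023s0061, which makes the galactolipid of plastid membranes, rose by 1.03 under OPDA in Tak-2 and 2.36 under wounding, and ACC1 Mapoly0002s0049, which makes malonyl-CoA, by 0.95 and 1.07. HISN1A Mapoly0157s0018, of histidine synthesis, rose by 1.27 and 0.88.

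The shared set also held 6 genes without description on scaffold 117, among them Mapoly0117s0056 and Mapoly0117s0053. Mapoly0117s0056 was 104-fold lower in Mpcoi1-1 and 160-fold lower in Mpcoi1-2 than in wild type, and rose 91.9-fold under coronatine. Mapoly0117s0053 was 82.7-fold and 135-fold lower, and rose 85.5-fold. The 6 are part of the 109 genes of the set, and 49 genes of the scaffold were tested. Chalcone synthase Mapoly0070s0063 fell 4.25-fold under OPDA in Mpcoi1-2 and the SAUR-like Mapoly0035s0025 4.50-fold (n = 2).

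The green local background was 413 to 1017 on slides 1 and 2 and 36 to 40.5 on slide 3, and the green negative controls 1250 to 3080 and 63.2 to 86.3. Of spots for 113 genes of the male sex chromosome, 15.7% to 19.5% were above background in red on the 8 arrays of male lines and 3.47% to 8.27% on the 9 of female lines. Array weights were lowest for replicate 3 of OPDA in Tak-2 (0.168) and highest for replicate 1 of Mpcoi1-2 against Tak-1 (4.65).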
